A study of Homo sapiens with 2 samples.

How the data were processed

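RNA sequencing was carried out on RKO cells, an established human colorectal cancer cell line, collected on day 2 after transfection with siRNA. The series holds 2 libraries, 1 from cells given a control siRNA and 1 from cells given an siRNA against hnRNPK. The labels' titles and protocol describe siRNA, whereas the genotype label of the second library is worded as a knockout. The groups are called control siRNA and hnRNPK siRNA here, after the titles and the protocol.

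The authors deposited 1 table of FPKM values (fragments counted relative to transcript length and library size) with 1 row per gene symbol and 1 column per library. Total RNA was harvested with Trizol and libraries followed Illumina's standard protocols, per the labels. Reads were processed with Bowtie 0.12.2 and the genome build was hg19, per the submitters' processing notes. The gene annotation, the counting method and its use of strand are not given in the sources used here. The control column was matched to its library by the abbreviation in the title, and the hnRNPK column by the letters Si and K in its name, which is a less direct match. No column of values was left unmapped.

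The table holds 40205 gene symbols, none of them repeated, and 21136 are listed at 0 in both libraries. Ratios between the columns were found to be fractions of whole reads times a constant, so the reads behind the FPKM values could be worked out. A fraction was called whole at a relative tolerance of 5e-14 and a length at a tolerance of 1e-05 bases. Of the 19069 genes above 0, 99.98% gave whole reads and a whole length. The smallest library totals that fit are 25729856 reads for control siRNA and 28550823 reads for hnRNPK siRNA. For each gene the smallest read numbers that fit were used, and the true numbers are these or a common multiple. Gene length in all that follows is the length recovered with those reads. For some genes it may be a whole fraction of the true length. Of the genes above 0 in both libraries, 99.2% had a ratio made of whole numbers up to 20000, against 0% after each ratio was divided by an irrational number. Exact Clopper-Pearson 95% intervals of each named gene's FPKM ratio were computed from these reads. They cover counting error only and leave out variation between cultures and libraries. Sequenced reads can also be copies of one molecule, which would make these intervals too narrow. The main analysis used the FPKM values, and no count model was fitted.

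Ratios were log2((FPKM + 1) in hnRNPK siRNA / (FPKM + 1) in control siRNA), a scale that understates the change of low genes. Genes with a mean FPKM of at least 1 over both libraries were kept, which left 11454 genes with a median of 632 reads in control siRNA and 592 in hnRNPK siRNA. With 1 library per group no test between conditions was possible, so genes were counted by a size rule of 2-fold and no p-value was computed.

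Gene lists were fixed before the data were examined, as were the size rule, the rule for named genes and the alternative settings, except those said below to have been added. There were 33 lists, of which 29 had at least 5 members with a mean FPKM of at least 1. For each, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list above the 97.5th percentile is called higher and one below the 2.5th percentile lower. The percentile describes these 2 libraries and not the conditions. If the lists were random, 1.45 of the 29 would lie outside by chance.

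The genes named are the siRNA target, a fixed panel, and the 10 highest and 10 lowest ratios among genes with a mean FPKM of at least 5, leaving out uncharacterised symbols and small RNAs. Small RNAs were recognised by fixed symbol patterns, which do not cover mitochondrial tRNAs such as TRNK. From each list outside the range they also include 3 members with the largest change in the list's direction and 1 with the largest change against it. From each other list they include up to 2 members changed at least 2-fold. These rules gave 87 genes, and some of these genes and 1 list are not reported here. Genes with near-identical copies, such as those of ribosomal proteins and histones, are uncertain, because reads can be shared with their copies or pseudogenes.

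Alternatives were a pseudocount of 0.1 or 5 FPKM, centring on the median of all genes, TMM factors, equal totals without small RNAs, summed rows per symbol, no filter or a mean FPKM of at least 5, folds of 1.5 and 3, small RNAs left out, 10 expression bins, the list mean, and lists without their most changed member. Matching on gene length as well, leaving out genes with certain sequence words, and requiring the counting interval to exclude no change were added after the data had been seen. Matching on length used 10 bins of expression and 20 bins of length, a number raised after simulated lists of short genes were not well matched with fewer bins and after the lists' values with fewer bins had been seen.

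Transcript sequences for base content and 3′ UTRs came from GENCODE 29, whose genome build differs from that of the authors, so no coordinates are given. The recovery of reads, the 2-fold rule, the list percentiles and the word search were tested on simulated data. Reads were recovered exactly for 85.6% of 18218 simulated genes and as a whole fraction for the others. Of 200 changed genes among 11450, the 2-fold rule found 72.0% of those changed 2.5-fold and 90.0% of those changed 4-fold. Counting error alone put 7 unchanged genes past the rule upwards and 20 downwards. Of 100 random lists of 30 genes drawn from 11454, 5 lay outside the range, and 100 of 100 shifted by 0.5 lay above it. Under a simulated length trend, 100 of 100 lists of short genes lay above the range, and 11 lay outside it once matched on length. A 7-base word given a fall of 0.1 ranked lowest in 20 of 20 simulations over 9884 genes, with the ratios shuffled over genes. Smaller shifts of lists or words were not simulated, and both words reported below have smaller means, −0.060 and 0.081. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.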

Results

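The transcriptome of RKO colorectal cancer cells was measured by RNA sequencing on day 2 after transfection with a control siRNA or an siRNA against hnRNPK, an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family. Each group has 1 library, so no difference given here has a replicate check. The smallest library totals that fit the values were 25729856 reads for control siRNA and 28550823 reads for hnRNPK siRNA. Intervals beside ratios are exact 95% counting intervals. These and the reads given for genes rest on the smallest read numbers that fit. The comparison asks which transcripts differ when hnRNPK is depleted.

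HNRNPK, the target of the siRNA, was at 338.0 FPKM in the control siRNA library and 61.5 FPKM in the hnRNPK siRNA library. This was 5.50-fold lower (5.27 to 5.73), which left 18.2% of the control level. The other genes of the fixed panel differed less. EGR1, an immediate early transcription factor, was at 12.5 FPKM in control siRNA and 7.54 FPKM in hnRNPK siRNA, a ratio of 0.604 (0.547 to 0.667). CFLAR, an inhibitor of caspase-8 activation, was at 1.30 and 0.612 FPKM, a ratio of 0.471 (0.394 to 0.563), but its mean FPKM is below 1, so it is in none of the counts below, and with 1 FPKM added it is not past 2-fold. The related poly(C)-binding proteins PCBP1 and PCBP2 had ratios of 1.39 (1.32 to 1.46) and 0.755 (0.734 to 0.776). The translation initiation factor EIF4E had a ratio of 1.25 (1.19 to 1.30), the kinase SRC 0.872 (0.795 to 0.957) and MYC 0.954 (0.925 to 0.983). SRC lay near the middle of all genes, with 46.8% of them at a lower ratio. For the ubiquitin ligase gene MDM2 the ratio was 0.972 (0.927 to 1.02), for the cyclin-dependent kinase inhibitor CDKN1A 0.967 (0.884 to 1.06) and for CTNNB1 1.04 (0.999 to 1.08), intervals that include 1 at the deposited scaling. After centring or with TMM factors MYC, MDM2 and CDKN1A lay on the higher side, and with equal totals CTNNB1 lay on the lower side, so the direction of these 4 genes is open.

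Across 11454 genes, 89 were at least 2-fold higher and 407 at least 2-fold lower in hnRNPK siRNA, while 10958 lay between. These counts, and those within lists, use FPKM + 1, whereas the ratios and folds printed for genes use FPKM alone. Log2 FPKM correlated between the libraries across genes, which are not independent replicates (Pearson r 0.972, Spearman rho 0.960). The median log2 ratio of all genes was −0.15, and some list medians are also given relative to it. The ratio correlated with mean log2 FPKM (Spearman rho 0.239 across 9992 genes), so lists of highly expressed genes tend to lie above that median, which the percentiles allow for and the counts of members above or below it do not. Centring on that median gave 142 genes higher and 241 lower, so that higher genes made up 37.1% of those past 2-fold against 17.9% as deposited, while TMM factors gave 36.3%. Equal totals without small RNAs moved it the other way, to 11.3%, with 68 higher and 535 lower. Without small RNAs 48 genes were higher and 394 lower. The counting interval excluded no change for 71 of the 89 higher genes and 394 of the 407 lower genes.

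**Figure D1:**
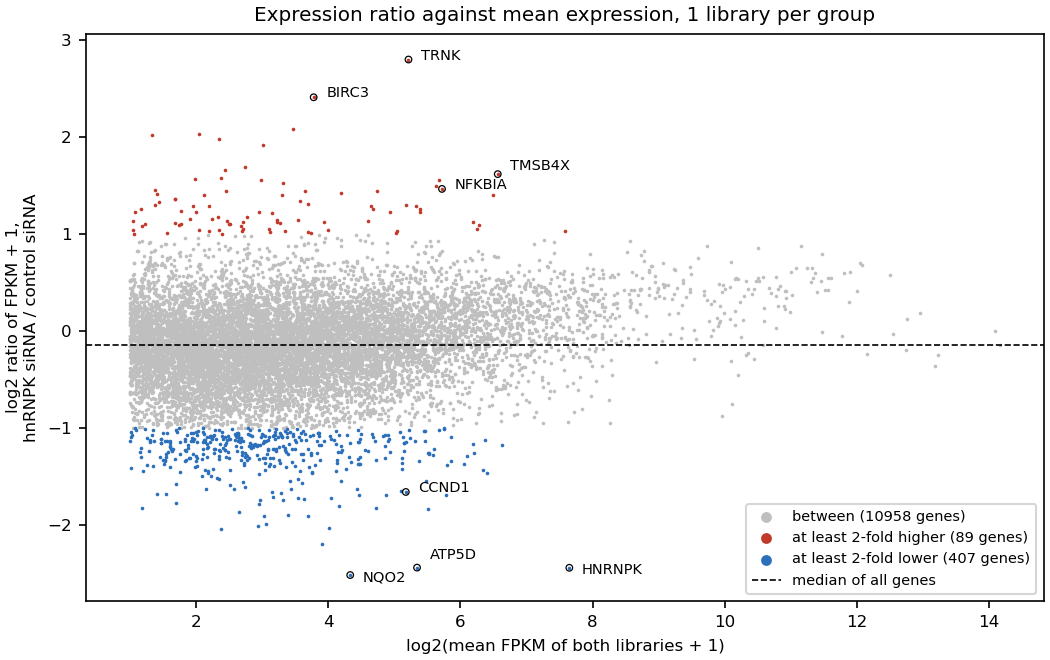
Log2 ratio of FPKM + 1 (hnRNPK siRNA over control siRNA) against the log2 of mean FPKM + 1, with 1 point for each of 11454 genes. The 89 genes at least 2-fold higher are red, the 407 at least 2-fold lower are blue, the dashed line is the median of all genes (−0.15), and circles mark 8 named genes, HNRNPK among the lowest.

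Among the 10 lowest ratios besides HNRNPK, that of NQO2, a quinone reductase, came from 33.4 FPKM in control siRNA and 5.01 FPKM in hnRNPK siRNA and was 6.65-fold lower (5.76 to 7.72). ATP5D, a subunit of the mitochondrial ATP synthase, was 5.80-fold lower (4.90 to 6.88), the carnitine acetyltransferase CRAT 5.37-fold (4.80 to 6.01) and MPC1, a subunit of the mitochondrial pyruvate carrier, 4.37-fold (3.39 to 5.68). XPC and ERCC1, both of nucleotide excision repair, were 4.50-fold (4.01 to 5.06) and 3.68-fold (3.50 to 3.88) lower. The others were PLCB3, SPA17, PAQR4 and SLFN5, between 4.65-fold and 5.51-fold lower.

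The highest ratio was that of TRNK, a mitochondrial lysine tRNA, at 8.33 and 64.0 FPKM from 15 and 128 reads, 7.69-fold higher (4.49 to 14.1). BIRC3, an inhibitor of apoptosis, was at 3.35 FPKM in control siRNA and 22.2 FPKM in hnRNPK siRNA, 6.61-fold higher (6.07 to 7.22). The serine protease PRSS22 was 4.94-fold higher (3.95 to 6.25), the actin-binding peptide gene TMSB4X 3.12-fold (2.87 to 3.39) and the cyclin-dependent kinase inhibitor CDKN2B 3.02-fold (2.75 to 3.32). EMP1, HIST1H1C, NFKBIA and FAM35A were between 2.83-fold and 3.03-fold higher. TMSB4XP8, a pseudogene, was 3.34-fold higher (2.54 to 4.44), and it is uncertain because it shares sequence with TMSB4X.

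Genes of sterol and fatty acid synthesis were lower in the hnRNPK siRNA library. Of 31 measured members, 9 were at least 2-fold lower, none was 2-fold higher and 27 lay below the median of all genes. The 9 became 7 after centring, 11 with equal totals and 2 with a pseudocount of 5 FPKM, by which LSS and SREBF2 were not past 2-fold. Lanosterol synthase, LSS, was at 6.60 FPKM in control siRNA and 1.64 FPKM in hnRNPK siRNA, 4.04-fold lower (3.46 to 4.74). SREBF2, the transcription factor that drives the pathway, was 2.99-fold lower (2.66 to 3.37), and IDI1, an isomerase of isoprenoid synthesis, was 2.65-fold lower (2.49 to 2.83). Against the direction of the list, the sterol desaturase SC5D was 1.20-fold higher (1.12 to 1.28). The list median was −0.74 on the log2 scale, or −0.60 relative to all genes, at the 0th percentile of random lists.

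Genes of DNA replication and repair were lower too. In the G1/S and replication list, 4 of 40 members were at least 2-fold lower and 27 lay below the median of all genes (median −0.36, 0th percentile). With a pseudocount of 5 FPKM 1 of 40 was, and neither POLA1 nor E2F1. The 4 became 3 after centring or with TMM factors and 5 with a pseudocount of 0.1 FPKM or equal totals. The DNA polymerase subunit POLA1 was at 14.8 and 5.21 FPKM and the transcription factor E2F1 at 12.7 and 4.45 FPKM in control siRNA and hnRNPK siRNA. GINS1, of the replicative helicase, went the other way at 9.13 and 17.1 FPKM. In the list of homologous recombination and Fanconi anaemia repair, 29 of 36 members lay below the median of all genes and 1 was at least 2-fold lower (median −0.51, 0.02th percentile). It was the endonuclease subunit EME1, 3.15-fold lower (2.66 to 3.75), and the checkpoint kinase ATR and the end-resection factor RBBP8 were at ratios of 0.441 (0.403 to 0.482) and 0.521 (0.491 to 0.553). ATR is past 2-fold by FPKM alone but not with 1 FPKM added, so it is not in that count. The count was 0 with a pseudocount of 5 FPKM, 3 with 0.1 FPKM and 2 with equal totals. MRE11A, which resects DNA ends, was at 1.21 (1.12 to 1.30).

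The G2/M and mitosis list lay nearer the other genes, with a median of −0.20 or −0.05 relative to all genes (1.35th percentile), and 1 of 43 members was at least 2-fold lower. That member was DLGAP5, a spindle protein, 3.30-fold lower (2.95 to 3.69). ASPM and CDC25C had ratios of 0.558 (0.532 to 0.584) and 0.555 (0.492 to 0.625), and securin, PTTG1, 1.38 (1.31 to 1.45). The ATF4 stress response list was at the 2.05th percentile (median −0.19, or −0.05 relative to all genes), with 1 of 31 members at least 2-fold lower, the cystine transporter SLC7A11 at 6.79 and 2.88 FPKM, which was no longer past 2-fold after centring, with TMM factors or with a pseudocount of 5 FPKM. CTH, WARS and DDIT4 had ratios of 0.530 (0.457 to 0.613), 0.638 (0.614 to 0.664) and 1.52 (1.40 to 1.65). The G2/M list was at the 3.70th percentile with the 28 of its 43 members that carry no 6-base start of either word, and the ATF4 list at the 5.02th percentile once matched on gene length and the 9.15th by its mean, so neither was then outside the range.

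Targets of NF-κB and inflammatory genes were higher in the hnRNPK siRNA library. Of 20 measured members, 6 were at least 2-fold higher, none was 2-fold lower and 19 lay above the median of all genes (median 0.56, 100th percentile). The 6 became 8 after centring or with TMM factors, 9 with a pseudocount of 0.1 FPKM and 2 with 5 FPKM, by which CXCL1 was not past 2-fold. BIRC3 was given above, and NFKBIA, which holds NF-κB in the cytoplasm, was at 27.1 FPKM in control siRNA and 76.6 FPKM in hnRNPK siRNA, 2.83-fold higher (2.64 to 3.03). The chemokine gene CXCL1 was at 0.326 and 2.17 FPKM from 5 and 37 reads, 6.67-fold higher (2.61 to 21.7). The cytokine gene LIF had a ratio of 0.842 (0.730 to 0.973). The interferon response list was within the range (median −0.23, or −0.09 relative to all genes, 22.4th percentile), with 0 of 30 members past 2-fold.

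**Figure D2:**
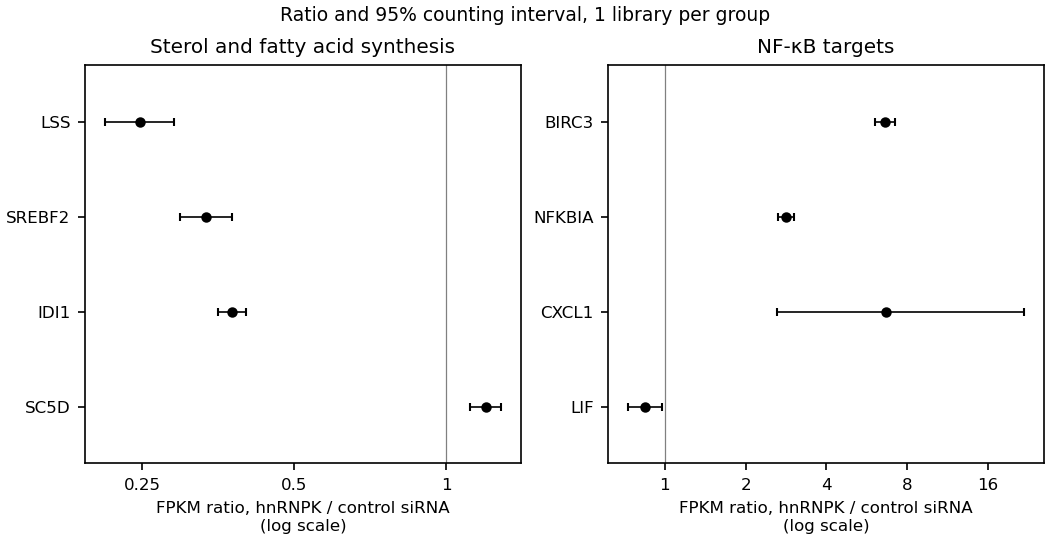
FPKM ratio (hnRNPK siRNA over control siRNA, log scale) of 4 members each of the sterol and fatty acid synthesis list and of the NF-κB list, with exact 95% counting intervals as bars. The 3 members chosen in each list's direction lie at 0.248 to 0.377 on the left and 2.83 to 6.67 on the right, and SC5D and LIF lie on the other side of 1.

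Genes of the ribosome and of translation were higher, by less than 2-fold at the deposited scaling. All 77 ribosomal protein genes lay above the median of all genes and none reached 2-fold (median 0.51, or 0.65 relative to all genes, 100th percentile). Random lists of like expression had a median of 0.21. Part of that distance may thus go with expression, though these random lists could hold ribosomal protein genes. RPL7A was at 1603 and 2946 FPKM, RPL34 at 594 and 1096 FPKM and RPS24 at 260 and 497 FPKM, while RPS29 was at 37.7 and 34.6 FPKM, a direction that turns after centring or with TMM factors. After centring or with TMM factors 3 of the 77, RPL7A, RPL34 and RPS24, were past 2-fold. Of 40 translation factors 33 lay above the median of all genes (median 0.29, 99.3th percentile), among them EEF1D, EIF3E and EIF5 at ratios of 1.65 (1.62 to 1.68), 1.60 (1.56 to 1.64) and 1.54 (1.49 to 1.59), while EIF2B3 was at 0.515 (0.431 to 0.614). MYC targets, mostly nucleolar proteins of ribosome production, had 31 of 40 members above the median of all genes (median 0.17, 99.6th percentile). NOP56 and NOLC1 had ratios of 1.76 (1.73 to 1.80) and 1.70 (1.65 to 1.76), NOP58 was at 204 and 306 FPKM, and ornithine decarboxylase, ODC1, was at 0.516 (0.494 to 0.539). The translation factor list was at the 94.7th percentile, within the range, when genes carrying a 6-base start of either word or with no 3′ UTR searched were left out, which left 20 of its 40 members.

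Of the 71 nuclear genes of oxidative phosphorylation, 53 lay above the median of all genes (median 0.17, 99.7th percentile). UQCR11 and ATP5J had ratios of 1.77 (1.54 to 2.04) and 1.44 (1.37 to 1.51), NDUFS5 was at 573 and 861 FPKM, and ATP5D, given above, was the 1 member at least 2-fold lower. Among 33 long non-coding RNAs, 25 lay above the median of all genes (median 0.30, 100th percentile), with ZFAS1, SNHG17 and PVT1 at ratios of 1.76 (1.68 to 1.83), 1.75 (1.62 to 1.88) and 1.80 (1.56 to 2.07), and OIP5-AS1 at 0.627 (0.591 to 0.665). Of 16 histone genes 12 lay above it (median 0.10, 99.2th percentile). The linker histone gene HIST1H1C was 2.89-fold higher (2.61 to 3.22), HIST1H3H and HIST1H3B rested on 12 reads each in control siRNA, and HIST2H2BE was 3.48-fold lower (2.58 to 4.76), but not past 2-fold on the FPKM + 1 scale after centring or with a pseudocount of 5 FPKM. The histone list was at the 84.7th percentile with the 7 members whose 3′ UTR was searched and had no 6-base start of either word. Once random lists were also matched on gene length, oxidative phosphorylation was at the 74.0th percentile and histones at the 78.8th, both within the range, though these random lists could hold ribosomal protein genes. By its mean, the oxidative phosphorylation list was at the 90.3th percentile.

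**Figure D3:**
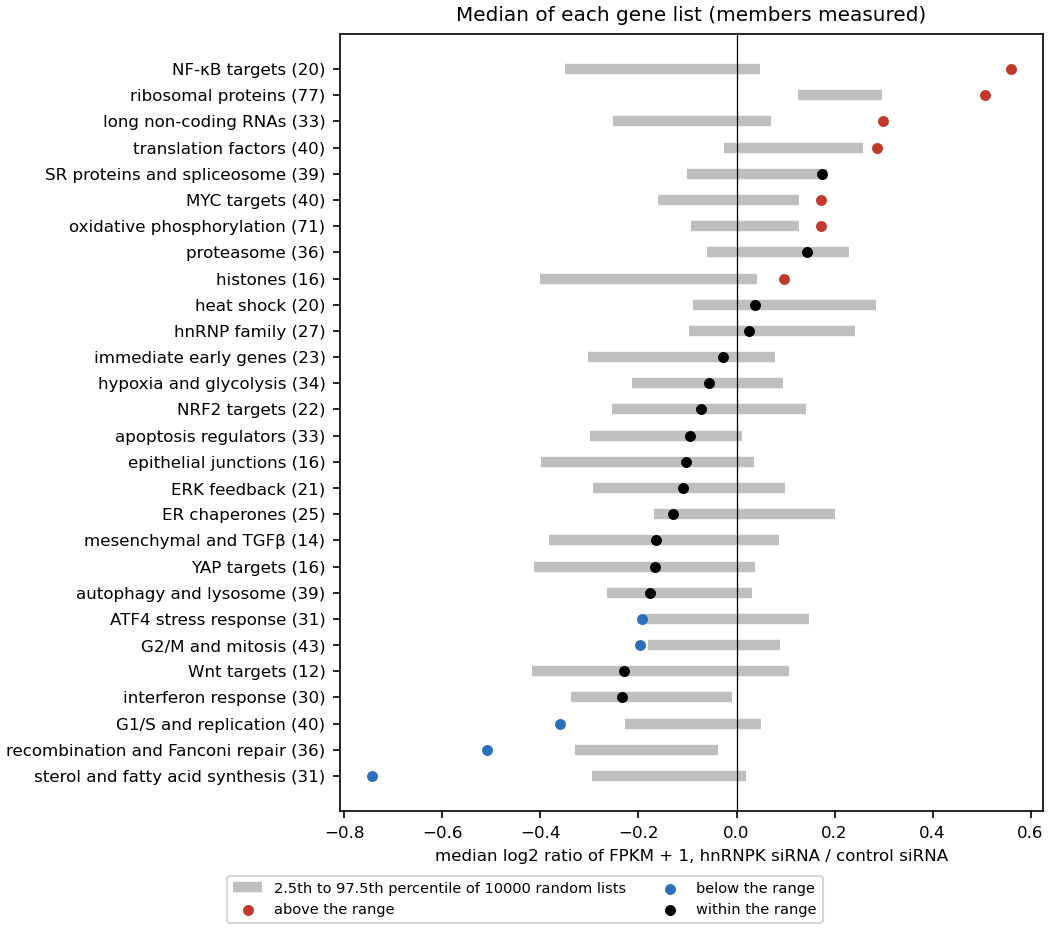
Median log2 ratio of FPKM + 1 (hnRNPK siRNA over control siRNA) of 28 gene lists, with measured members in brackets, over the range of 10000 random lists matched on expression that was used to call lists (grey bars). The 7 lists above the range are red and the 5 below it blue, from the NF-κB list at 0.56 to sterol and fatty acid synthesis at −0.74.

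The other lists lay within the range by their medians at the main settings. SR proteins and spliceosome components were at the 96.6th percentile, or above the range at the 97.8th among genes with a mean FPKM of at least 5, with PRPF3 2.73-fold lower (2.43 to 3.07), and hnRNP family genes at the 30.8th, with a median of 0.03, of either sign by scaling, and a mean of −0.04. Endoplasmic reticulum chaperones were at the 5.91th percentile, or the 0.54th by their mean, with SEC24D 3.79-fold lower (3.30 to 4.35), hypoxia and glycolysis at the 53.7th with SLC16A3 and HK2 2.92-fold (2.63 to 3.24) and 2.15-fold lower (2.06 to 2.25), and immediate early genes at the 81.3th with KLF2 3.94-fold lower (2.98 to 5.28). Wnt targets were at the 26.0th percentile and ERK feedback genes at the 44.6th, and both hold cyclin D1, CCND1, which was at 53.9 and 16.4 FPKM. The Wnt target EPHB2 was 2.99-fold lower (2.61 to 3.44). YAP targets were at the 55.1th percentile with NT5E and ASAP1 4.02-fold (3.27 to 4.97) and 2.29-fold lower (2.16 to 2.43), and mesenchymal genes at the 44.9th with TAGLN at 0.549 and 2.90 FPKM. Heat shock genes were at the 27.0th percentile, epithelial junctions at the 76.4th, NRF2 targets at the 45.9th, autophagy and lysosome at the 19.8th and the proteasome at the 72.0th. Apoptosis regulators were at the 73.9th, with a median of −0.09, of either sign by scaling, and a mean of 0.05 at the 99.7th percentile. BIRC3, given above, is the 1 member of that list past 2-fold, and the mean without it was not computed. Of the genes in this paragraph, HK2 and ASAP1 were no longer past 2-fold after centring or with TMM factors, and with a pseudocount of 5 FPKM neither these nor SEC24D, KLF2, EPHB2, NT5E and TAGLN were.

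Among the genes named above, the word ATGGAAA was found in the 3′ UTRs of EIF4E, CFLAR, SRC, PCBP2, SLFN5, MPC1, EMP1, CDC25C, HIST2H2BE, ODC1, SLC7A11, SLC16A3, HK2 and EPHB2. The word CTAAGAA was found in those of MDM2, PCBP1, NQO2, SLFN5, ERCC1, EMP1, CDKN2B, FAM35A, GINS1, SLC7A11, WARS and EPHB2. Both words occur with either direction of ratio here, and 2411 and 1336 of 9884 genes searched carry them. Their relation to the ratio is described with the other observations.

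Markers of other cells were mostly near 0. Of 21 blood cell markers 1 had a mean FPKM of at least 1, CD68, a lysosomal protein, at 307 FPKM in control siRNA and 193 FPKM in hnRNPK siRNA. Of 18 stromal and endothelial markers it was ACTA2 at 1.35 and 2.79 FPKM, and of 16 neuron and muscle markers GAD1 at 1.45 and 1.90 FPKM and TUBB3 at 7.07 and 2.26 FPKM. Of 33 intestinal differentiation genes 2 were measured, CDX2 at 5.01 and 4.47 FPKM and CA2 at 8.44 and 12.7 FPKM. The median of each of these 4 lists was 0 FPKM in both libraries.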

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

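Matching lists on gene length, leaving out genes with a sequence word and requiring the counting interval to exclude no change were tests chosen after the result was seen. The log2 ratio of HNRNPK, −2.44, was −2.37 with a pseudocount of 5 FPKM, −2.29 after centring, −2.27 with TMM factors and −2.54 with equal totals. The 89 genes at least 2-fold higher and 407 lower became 162 and 754 with a pseudocount of 0.1 FPKM, 24 and 85 with 5 FPKM, 142 and 241 after centring, 149 and 261 with TMM factors, and 50 and 258 at a mean FPKM of at least 5. At 1.5-fold they were 420 and 1682, and at 3-fold 10 and 39. Leaving out small RNAs gave 48 higher genes. Pearson r, 0.972, was 0.985 with no filter and 0.965 with a pseudocount of 0.1 FPKM. A pseudocount, a fold limit, a rescaling of all genes and leaving genes out each change the counts of genes by construction. The scalings moved the median log2 ratio by 0.15 (centring), 0.15 (TMM factors) and −0.09 (equal totals). Why that median lies off 0 as deposited was not tested.

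The number of lists above the range stayed between 5 and 8 and the number below it at 4 or 5. Lists of sterol synthesis, G1/S, recombination repair, NF-κB, ribosomal proteins and MYC targets kept their side of the range in all 13 alternatives, and long non-coding RNAs in all 12 that could be run. The ATF4 list kept it in 8 of 13, histones in 10 of 12, oxidative phosphorylation in 11 of 13, and G2/M and translation factors in 12 of 13. Summing rows per symbol moved nothing because no symbol was repeated. Centring shifts a list and its random lists by the same amount, so it could not change a percentile. TMM factors and equal totals shift them by nearly the same amount. The alternatives counted above thus include settings that could not, or could hardly, move a list. No paired analysis was possible because each group has 1 library. Few reads limit some genes, such as CXCL1, 6.67-fold higher with an interval of 2.61 to 21.7. The reads used are the smallest that fit, and a multiple of them would narrow the interval.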

Other observations

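The tests in this part were chosen after the result was seen, except the comparisons of words with the same bases in another order. The 15 mitochondrial genes looked at here, chosen after their values were seen, made up 20.6% of total FPKM in control siRNA and 18.4% in hnRNPK siRNA, with a median log2 FPKM ratio of −0.03. ND3, a subunit of complex I, was at 3233 and 5255 FPKM, and ATP8, of the ATP synthase, at 10439 and 8168 FPKM.

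The sequence of 3′ UTRs was related to the ratio: after looks at gene length and base content, all 16384 words of 7 bases were searched in 9884 genes, and of the 16139 found in at least 50 genes ATGGAAA had the lowest ratio adjusted for expression and 3′ UTR length (2411 genes, mean −0.060, z −7.37) and CTAAGAA the highest (1336 genes, mean 0.081, z 7.41). Chance is argued against by 100 shuffles of the genes, which reached −5.22 and 4.51. Other orders of the same bases without the word's first 6 bases reached −3.51 and 2.98, which argues against base composition. Orders that hold those 6 bases overlap the word and were left out. They were AATGGAA at −5.90 and ACTAAGA at 4.44. A candidate explanation is seed pairing of the hnRNPK siRNA with ATGGAAA and of the control siRNA with CTAAGAA: words chosen in 1 of 2 random parts of the genes differed in the other part from their first 6 bases alone by −0.075 (95% bootstrap interval −0.10 to −0.050) for the lowest, which pools ATGGAAA and TATGGAA as chosen by the 2 parts, and 0.054 (0.025 to 0.081) for CTAAGAA, which both parts chose, so that the value is that of all genes searched. Of the −0.075, part comes from the comparison groups: the 2 lowest words were at −0.051 and −0.055 and their first 6 bases alone at 0.021 and 0.024. Over all genes searched, ATGGAA without ATGGAAA was at 0.014, CTAAGA without CTAAGAA at 0.027 and neither 6-base start at 0.0017. The 6 bases ATGGAA alone thus went with no fall. Genes with ATGGAAA outside the 3′ UTR and not its 6-base start inside it also had a negative mean adjusted ratio (1248 genes, −0.038), whereas those with CTAAGAA placed likewise were at 0.004 (779 genes). The HNRNPK transcript searched holds ATGGAAA, with TATGGAAA once, and does not hold CTAAGAA. TATGGAAA is in 12.9% of the transcripts searched, so its presence in HNRNPK decides little. The 726 genes with TATGGAAA in the 3′ UTR had a mean adjusted ratio of −0.085. The siRNA sequences are not given in the sources used here, and a microRNA or RNA-binding protein that reads the same words could give these values too.

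Sterol and fatty acid synthesis genes were lower in hnRNPK siRNA (median −0.74). Sites of the 2 words in the members' own 3′ UTRs are argued against as the whole cause. The 12 members with neither 6-base start there had a median of −0.65, at the 0.1th percentile of matched genes with neither. This covers neither words outside the 3′ UTR nor words in other genes. Gene length, as recovered with the reads, is argued against as the whole cause, with the list at the 0th percentile once matched on it. A difference between the 2 cultures and an effect of hnRNPK cannot be told apart, since each group has 1 library.

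Ribosomal protein genes were higher (median 0.51). Genes of shorter recovered length had higher ratios in general, with a median of 0.05 in the shortest 20% and −0.23 in the longest 20%. Recovered length and GC content are argued against as the whole cause. The list was at the 100th percentile when matched on expression and that length. Random lists, which could hold its own members, then had a median of 0.26. The list was also at the 100th percentile when matched on expression and GC content. Recovered lengths can be a fraction of the true ones, so the matching on length was imperfect. A difference between the cultures stays open here too, as does an effect of hnRNPK, and neither was tested.

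A loss of C-rich mRNAs, which hnRNPK binds, was tested across 9992 genes. The ratio correlated with the C content of the 3′ UTR at rho −0.072 and with its G content at −0.065, a difference of −0.0069 (95% bootstrap interval −0.023 to 0.0091), so these values leave the hypothesis undecided. Genes are not independent replicates.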
